A study of Mus musculus with 6 samples.

How the data were processed

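The arrays were Affymetrix Mouse Gene 1.0 ST arrays, whose probe sets summarise probes spread along a whole gene. Per the labels' protocols, total RNA was extracted from FAPs frozen after isolation, and biotin-labelled single-stranded cDNA was made from 100 ng of it. Per the labels, each of the 6 samples is a separate pool of cells from 4 mice, with 2 samples in each of 3 groups. The deposited values are on a log2 scale. Per the submitters' processing notes they were made with Affymetrix Expression Console by RMA, a method that corrects background, makes the distributions of the arrays alike and summarises the probes of a probe set. The settings and the version of that software are not given in the sources used here. RMA makes the arrays' distributions alike, so a change in the total amount of RNA per cell cannot be seen in these values. It also compresses changes of dim probe sets. The deposited log2 values ran from 1.38 to 13.50, and the correlation between any pair of arrays over all probe sets was 0.99. No scanner files or dates of scanning were used here, so a batch of arrays could not be tested.

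The value table held 35556 probe sets. In the platform annotation used here 21789 of them have 1 gene symbol, 1621 have several and 12146 have none. Probe sets with several symbols or none were not named. Of the named probe sets, 21698 have a gene ID in a RefSeq gene table (GRCm38.p6), and 0 symbols had to be updated. They stand for 19938 genes. For the 999 genes with several probe sets, the probe set with the highest mean over all arrays was taken. Genes with a mean below the 25th percentile (log2 5.209) were left out, which left 14953 genes.

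Group means were fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes without trend, not robust) on all 6 arrays, with no block. The groups thus share one estimate of the spread, with 3 residual and 6.06 prior degrees of freedom. The 3 comparisons were pA-VMO against control VMO, 5'ss-VMO against control VMO and pA-VMO against 5'ss-VMO. Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Changes are differences of log2 values, and folds are computed from them. An exact permutation of 2 against 2 arrays cannot reach p = 0.05, so genes were called only with a test that shares the spread across genes.

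Before the data were examined, 33 gene lists with 729 members were fixed: markers of FAPs and of the other cells that could be present in muscle, and genes of pathways that bear on fibrosis, growth, stress and inflammation. Of the members 676 were on the array and 644 were tested. Erythroid markers had 3 tested members, below the minimum of 5, and were not tested, which left 32 lists. Lists were tested with camera (limma) at the preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 32 lists of a comparison, and members were also adjusted over the list alone. Camera compares the members of a list with all other genes. With a correlation estimated from the residuals, 0 lists were called in any comparison, where 3 lists had an unadjusted p under 0.05 for pA-VMO against control, 2 for 5'ss-VMO against control and 5 for pA-VMO against 5'ss-VMO. That form of the test rests on the 3 residual degrees of freedom, so few lists can pass it whatever their correlation. The Schwann cell list between the reagents had an estimated correlation of -0.0264, below the preset value. Its unadjusted camera p still went from 0.00202 to 0.0496. A call lost with this form therefore does not show that a list is unchanged. Other lists had estimated correlations far above the preset value of 0.01. They were 0.401 for interferon-stimulated, 0.574 for G2 and M, 0.383 for S phase and 0.402 for contractile genes. For such lists the camera p at the preset correlation may be much too small. At the preset correlation 15, 13 and 11 lists were called. The fry test, which asks whether the genes of a list move one way on balance without comparing them with other genes, called 0, 2 and 6 lists.

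The rule for named genes was also fixed before the data were examined. Pdgfra came first. Then, per comparison, up to 12 genes of each direction with the largest change among those called were named. Where fewer passed, genes of that direction with the smallest p whose arrays of one group both lay beyond those of the other were added and given as values that did not pass. Up to 4 members with the smallest p were taken from each called list and each marker list. Predicted genes without a name, olfactory and vomeronasal receptors, microRNAs and small nucleolar or nuclear RNAs were counted and not named.

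The procedure was tested on simulated data with the means and the spread of the 14953 genes, for 5'ss-VMO against control VMO, in 20 runs with 200 changed genes. It recovered 84.7% of genes changed by 0.5 (log2), 99.4% of those changed by 1 and 100% of those changed by 2, with 5.15% of the calls false. With no change simulated it made 0.05 calls per run on average. A list shifted by 0.3 was called in 100% of the runs, and with no shift 0.05 lists were called per run. The simulation drew genes independently, so it does not test the lists against correlated genes. The share recovered depends on how many genes change and by how much. It therefore does not carry over to a comparison with fewer or smaller changes, such as pA-VMO against control, where 1 gene was called.

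The alternatives tried were no filter, a filter at the 50th percentile, cyclic loess and median centring on top of the deposited values, eBayes with trend and robust, array quality weights, a fit on the 4 arrays of a comparison, the replicate number as a block, the mean over the probe sets of a gene, an adjusted p threshold of 0.1, each array left out in turn, and for lists the estimated correlation and fry. Where an array was left out, its group had 1 array, whose spread was assumed to equal that of the other groups. For the comparison of the 2 changes against control, 100 sets of unchanged groups with shared controls were simulated. Intervals of list levels are 95% intervals from the spread between the arrays of a group (3 degrees of freedom). They use the spread of each list alone and are not adjusted for the number of lists. A list whose arrays happen to lie close together thus gets a narrow interval. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.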

Results

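Gene expression was measured in fibro/adipogenic progenitors (FAPs), the mesenchymal stromal cells of skeletal muscle that can become fibroblasts or adipocytes. The cells came from male C57BL/6 mice whose tibialis anterior muscles had been injured by an injection of 30 µL of 50% glycerol, a chemical injury that is followed by deposition of fat and scar tissue. A vivo-morpholino (VMO), a synthetic antisense oligomer with a delivery group that blocks a chosen site on an RNA in the living animal, was given 3 days after the injury, and the cells were taken 2 days after that. There were 3 groups, treated with a control VMO, with VMO against polyadenylation sites (pA-VMO) or with VMO against a 5' splice site (5'ss-VMO). The target was the transcript of Pdgfra, the gene of platelet-derived growth factor receptor alpha. Each group had 2 arrays, and each array held the RNA of cells pooled from 4 mice. All 6 arrays gave log2 values for 35556 probe sets, and 14953 named genes were compared. The SD of the difference between the 2 arrays of a group, taken over genes, was 0.13 on the log2 scale with control VMO, 0.12 with pA-VMO and 0.13 with 5'ss-VMO. The number of arrays limits the precision: the median standard error of a change between groups was 0.07, and an exact permutation of 2 against 2 arrays cannot give a p below 0.333. All adjusted p values of genes below are from limma with Benjamini-Hochberg adjustment, two-sided.

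The study concerns a shortened Pdgfra transcript that ends at a polyadenylation site inside an intron; pA-VMO was meant to lower its share and 5'ss-VMO to raise it. The level of Pdgfra was therefore read first in every array. Pdgfra lies on chromosome 5 from 75151322 to 75198206 in GRCm38.p6, and 1 probe set of the array is annotated to it. Its log2 level was 11.37 and 11.24 on the control arrays, 11.29 and 11.32 on the pA-VMO arrays, and 11.31 and 11.29 on the 5'ss-VMO arrays. Pdgfra differed from control by 0.001 ± 0.069 (log2, SE, n = 2 arrays per group) with pA-VMO (adjusted p = 0.997) and by -0.005 ± 0.069 with 5'ss-VMO (adjusted p = 0.984). The difference between the 2 reagents was 0.006 ± 0.069 (adjusted p = 0.979). The 95% intervals of the 3 differences lay between -0.16 and 0.16. The probe set reads the gene as a whole and does not separate the shortened from the full transcript, so it checks neither the reagents nor the labels.

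Treatment with 5'ss-VMO was followed by a rise of interferon-induced genes. Ifi213 rose by 1.39 ± 0.129 (log2, SE; 2.62-fold, adjusted p = 0.00382), Ifi208 by 1.32 ± 0.1 (2.49-fold, adjusted p = 0.0016) and Ifi206 by 1.06 ± 0.069 (2.09-fold, adjusted p = 0.0012). These 3 genes and Ifi209, which rose by 1.00 (adjusted p = 0.0104), belong to the Ifi200 family of interferon-inducible DNA sensors. The interferon-induced gene Mx1 rose by 0.99 (1.98-fold, adjusted p = 0.0276) and Oas2, which senses double-stranded RNA, by 0.82 (1.76-fold, adjusted p = 0.00215). Gbp4, a guanylate-binding protein, rose by 0.86 (adjusted p = 0.0344) and the interferon-induced gene Cxcl11 by 0.81 (adjusted p = 0.0151). Of other genes, the membrane protein genes Ms4a4c and Ms4a6c rose by 1.02 and 0.76 (adjusted p = 0.0014 and 0.00551), Phf11a by 0.81 (adjusted p = 0.0104) and Lrrn1, a leucine-rich repeat membrane protein, by 0.91 (adjusted p = 0.00239). Lrrn1 lay at 4.93 and 4.87 on the control arrays, below the filter floor of 5.209. It was below that floor with pA-VMO too and passed the filter through the 5'ss-VMO arrays (5.85 and 5.77). Ifi209 was also below the floor on the control arrays, at 4.91 and 5.2. The Ifi200, Ms4a, Gbp and Oas genes have close paralogs on which their probes may read, so the share of each single gene in these rises is uncertain. In all, 87 of 14953 genes passed an adjusted p of 0.05 with 5'ss-VMO, 75 of them higher and 12 lower than control, and 5 of the 87 were predicted genes or small RNAs outside the naming rule. The count was 8 without control replicate 1, 26 without control replicate 2, 42 without 5'ss-VMO replicate 1 and 31 without 5'ss-VMO replicate 2. Of the 12 genes named above, Ifi213, Ifi208, Ifi206, Ms4a4c, Lrrn1 and Oas2 were called whichever array was left out, while the adjusted p of the others reached up to 0.188.

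Fewer genes fell with 5'ss-VMO than rose. Kera, the keratan sulfate proteoglycan keratocan, fell by 0.69 ± 0.12 (log2, SE; 1.62-fold lower, adjusted p = 0.0474). Dpp4, a surface peptidase that marks a subset of muscle fibroblasts, fell by 0.52 (adjusted p = 0.0318) and Wif1, a secreted Wnt inhibitor, by 0.41 (adjusted p = 0.0415). The other named genes that fell were Chl1 by 0.67 (adjusted p = 0.0276), Ifi27, which is interferon-induced and thus goes against the rise above, by 0.67 (adjusted p = 0.00802), Lgi3 by 0.60 (adjusted p = 0.0172), and Anxa8 by 0.52 (adjusted p = 0.0415). Smaller falls were those of Polr2k by 0.50 (adjusted p = 0.0313), Wfdc10 by 0.47 (adjusted p = 0.0348), Cyp2f2 by 0.46 (adjusted p = 0.029) and Colgalt2, a collagen galactosyltransferase, by 0.38 (adjusted p = 0.0386). Lum, a collagen-binding proteoglycan, lay at -0.33 and did not pass the test (adjusted p = 0.0636). None of the 11 named calls passed in all 6 fits that left out 1 array (limma, adjusted p up to 0.239), and all 11 kept their sign in those fits.

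The list of interferon-stimulated genes rose as a group with 5'ss-VMO. All 26 measured members had a positive change, with a mean of 0.44 (log2), and 25 had both 5'ss-VMO arrays above both control arrays. Of the 26, 12 rose over all genes tested and 24 rose when adjusted over the list alone. Examples beside Mx1 and Oas2 were Ifit2, which rose by 0.73 (adjusted p = 0.0105), the chemokine Cxcl9 by 0.53 (adjusted p = 0.0131) and Bst2, which tethers virus particles, by 0.52 (adjusted p = 0.0131). The camera test with its preset correlation gave the list an adjusted p of 2.33e-29, and it gave an adjusted p = 0.454 with an estimated correlation. From the spread between arrays, the 95% interval of the mean change was 0.256 to 0.617. The number of members called over all genes was 1 without control replicate 1, 3 without control replicate 2, and 1 without either single 5'ss-VMO array, while the mean change stayed between 0.39 and 0.49. Markers of macrophages moved with this list, with a mean change of 0.29 over 17 markers and a camera adjusted p of 5.17e-09 (adjusted p = 0.454 with an estimated correlation). The 95% interval between arrays for these markers was 0.081 to 0.501. Of these, the complement genes C1qc and C1qa rose by 0.50 (adjusted p = 0.0249) and 0.39 (adjusted p = 0.0472), 9 rose when adjusted over the list alone, and Ms4a7 lay at 0.58 (adjusted p = 0.0707).

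**Figure D1:**
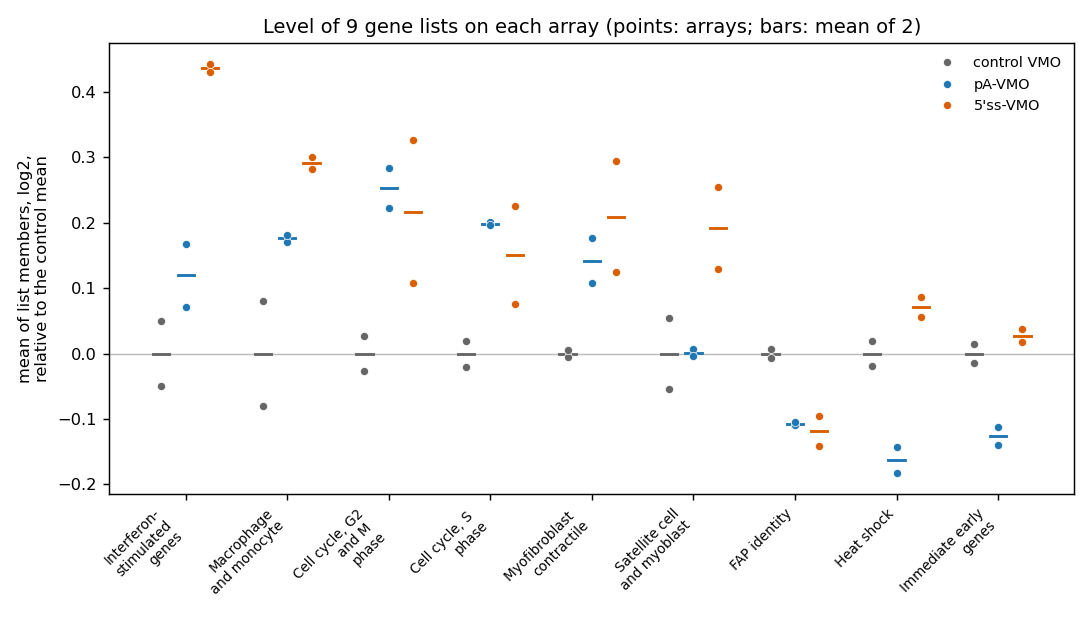
Mean log2 level of 9 gene lists on each of the 6 arrays, given relative to the mean of the control arrays; points are arrays and bars are the mean of the 2 arrays of a group. The interferon-stimulated list lay at 0.44 and 0.43 on the 5'ss-VMO arrays and at 0.07 and 0.17 on the pA-VMO arrays, and the heat shock list lay below both control arrays with pA-VMO only.

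Cell cycle and contractile genes were also shifted upward with 5'ss-VMO. The list of the G2 and M phases had 28 of 29 members higher than control with a mean change of 0.22, of which 0 rose over all genes and 10 rose when adjusted over the list alone (camera adjusted p = 7.61e-10). Mki67, the proliferation marker, lay at 0.57 (adjusted p = 0.0517) and the kinesin Cenpe at 0.42 (adjusted p = 0.141). The S phase list had a mean change of 0.15 with 0 of 27 members called by either adjustment (camera adjusted p = 1.47e-06). The myofibroblast contractile list had a mean of 0.21 (camera adjusted p = 1.09e-06), with 0 of 20 members called over all genes and 11 higher when adjusted over the list alone. The smooth muscle genes Tagln and Cnn1 both lay at 0.53 (adjusted p = 0.111 and 0.0983). With an estimated correlation all 3 lists had an adjusted p = 0.473. The 95% intervals from the spread between arrays included 0 for all 3 lists. They were -0.086 to 0.52, -0.051 to 0.353 and -0.028 to 0.447 in the order given. The shift of the G2 and M list was 0.11 without 5'ss-VMO replicate 2 and 0.33 without 5'ss-VMO replicate 1, that of the S phase list 0.08 and 0.23, and that of the contractile list 0.13 and 0.29, and the lists stayed called in these fits. Without 5'ss-VMO replicate 2 Cenpe lay at 0.27 and Tagln at 0.33.

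Markers of FAPs fell as a list with 5'ss-VMO, while markers of several other cells of muscle were shifted upward. The FAP list had a mean change of -0.12 over 19 markers (camera adjusted p = 0.000479; adjusted p = 0.454 with an estimated correlation), with Dpp4 as the single member that fell over all genes tested and 2 that fell when adjusted over the list alone. Satellite cell and myoblast markers had a mean change of 0.19 (camera adjusted p = 0.000215; adjusted p = 0.473 with an estimated correlation). Of the 14 members Chrna1, the muscle acetylcholine receptor subunit, rose by 0.62 (adjusted p = 0.0283), 5 rose when adjusted over the list alone, and Des and the fusion gene Mymk lay at 0.49 and 0.43 (adjusted p = 0.0707 and 0.0948). The 17 muscle fibre markers had a mean change of 0.13, with 0 called over all genes and 5 when adjusted over the list alone (camera adjusted p = 0.00943, adjusted p = 0.53 with an estimated correlation). Over the settings tried that mean ran from 0.065, without control replicate 1, to 0.203. The 11 pericyte and smooth muscle markers had a mean of 0.15 (camera adjusted p = 0.0246; adjusted p = 0.454 with an estimated correlation); of these Mcam rose by 0.42 (adjusted p = 0.0443) and 3 rose when adjusted over the list alone. The 8 Schwann cell markers had a mean of -0.10, with 0 called over all genes and 3 lower when adjusted over the list alone (camera adjusted p = 0.0352, adjusted p = 0.454 with an estimated correlation). Judged by the spread between arrays, the 95% intervals included 0 for the satellite cell (-0.023 to 0.406) and fibre (-0.058 to 0.327) lists. Those of the FAP, pericyte and Schwann lists did not. The SD between arrays was 0.02 for the FAP and Schwann lists and 0.008 for the pericyte list. For the satellite cell list it was 0.067. Without control replicate 1 the fibre, pericyte and Schwann lists were not called (adjusted p = 0.45, 0.0569 and 0.0558), nor was the Schwann list without control replicate 2 (0.0979), nor were the pericyte and Schwann lists without 5'ss-VMO replicate 1 (0.0607 and 0.0739). Endothelial, lymphocyte, neutrophil and tenocyte markers were not called (camera adjusted p = 0.0524, 0.587, 0.11 and 0.588), although the endothelial cadherin Cdh5 rose by 0.70 (adjusted p = 0.00551).

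Among the remaining lists, cytokines and chemokines and collagens were shifted upward with 5'ss-VMO and readouts of Hedgehog, Wnt and BMP signalling downward. The 30 cytokines and chemokines had a mean change of 0.10 (camera adjusted p = 0.0165, adjusted p = 0.559 with an estimated correlation), with the eosinophil chemokine Ccl11 as the 1 member that rose over all genes, by 0.46 (adjusted p = 0.0422). When adjusted over the list alone 5 rose, and Il1b lay at 0.64 (adjusted p = 0.0524). The collagen list had a mean of 0.09 (camera adjusted p = 0.0226, adjusted p = 0.672 with an estimated correlation). Of its 20 members 0 rose over all genes and 3 rose when adjusted over the list alone; Col12a1 and Col8a1 lay at 0.31 and 0.28 (adjusted p = 0.179 and 0.116). The 24 signalling readouts had a mean of -0.09 (camera adjusted p = 0.0246, adjusted p = 0.454 with an estimated correlation), with Wif1 as the 1 member that fell over all genes. When adjusted over the list alone 3 fell, and Gdf10, a BMP-related ligand, lay at -0.40 (adjusted p = 0.0831). By the spread between arrays, the 95% intervals of the cytokine (-0.06 to 0.261) and collagen (-0.03 to 0.2) lists included 0. That of the signalling readouts did not (-0.148 to -0.029). Without 5'ss-VMO replicate 1 these 3 lists had an adjusted p of 0.228, 0.253 and 0.0892; without control replicate 1 the cytokine and signalling lists had 0.0859 and 0.11, and without control replicate 2 the collagen list had 0.146. The matrix, matrix protease and TGF-beta target lists had mean changes of 0.03, -0.05 and -0.01 and were not called (camera adjusted p = 0.424, 0.315 and 0.689). The other lists not called had adjusted p values from 0.0524 to 0.908.

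Treatment with pA-VMO left most single genes below the threshold. Kera fell by 1.32 ± 0.12 (log2, SE; 2.50-fold lower, adjusted p = 0.0232), from 7.97 and 7.71 on the control arrays to 6.52 on both pA-VMO arrays, and was the 1 gene of 14953 called. At an unadjusted p under 0.05 there were 1712 genes, where chance alone would give 747.7. With either control array or either pA-VMO array left out, Kera lay between -1.45 and -1.19 and missed the threshold (limma adjusted p = 0.19 and 0.144 without control replicates 1 and 2, 0.261 and 0.0856 without pA-VMO replicates 1 and 2). It also missed it when no genes were filtered out (adjusted p = 0.134). The other genes singled out for their small p did not pass the test, with adjusted p values of 0.154 to 0.204. Above control lay Ifi213 at 0.78, Mki67 at 0.58, Ms4a6d at 0.53, Ptprn at 0.52, Kcnk10 and the osteoprotegerin gene Tnfrsf11b at 0.42, the condensin gene Ncapg at 0.38, Oas2 at 0.37, the macrophage marker Cd68, Lrrc29 and Fam78b at 0.35 and Rnf213 at 0.34. Below control lay P2ry10b at -0.75, Anxa8 at -0.64, Amy1 at -0.56, Clip4 at -0.55, Sema3c at -0.50, Cyp2f2 at -0.46, C1qtnf1 at -0.45, the heat shock gene Hspa1a and Car5b at -0.41, Tcim at -0.40 and the cartilage matrix gene Comp at -0.38.

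Cell cycle lists were shifted upward with pA-VMO. The 29 members of the G2 and M list all had a positive change, with a mean of 0.25 (camera adjusted p = 7.59e-14), and 26 of the 27 members of the S phase list did, with a mean of 0.20 (camera adjusted p = 1.32e-10). Over all genes tested 0 members of either list rose, and 13 and 12 rose when adjusted over the list alone. Plk1, a mitotic kinase, lay at 0.52 (adjusted p = 0.244), Kif11, a spindle motor, at 0.33 (adjusted p = 0.243), and the replication licensing genes Mcm7 and Mcm5 at 0.46 and 0.31 (adjusted p = 0.222 and 0.278). Both lists had an adjusted p = 0.473 with an estimated correlation. Cholesterol synthesis genes had a mean change of 0.16 (camera adjusted p = 0.00301; adjusted p = 0.482 with an estimated correlation), with 0 of 20 members called over all genes and 6 higher when adjusted over the list alone. The sterol demethylase Cyp51 lay at 0.62 (adjusted p = 0.252), and at 0.39 without control replicate 2. The myofibroblast contractile list had a mean of 0.14 (camera adjusted p = 0.000533; adjusted p = 0.482 with an estimated correlation), with 0 of 20 members called over all genes or when adjusted over the list alone. In it Tagln and Acta2 lay at 0.37 and 0.33 (adjusted p = 0.328 and 0.35). The 30 ribosome biogenesis genes, of which 0 were called in either way, had a mean of 0.09 (camera adjusted p = 0.00176, adjusted p = 0.55 with an estimated correlation). That list was not called without control replicate 2 or without pA-VMO replicate 2, where its mean was 0.047 and 0.044. For all of these lists the 95% interval from the spread between arrays included 0. It was -0.05 to 0.557 for G2 and M, -0.004 to 0.401 for S phase and -0.118 to 0.427 for cholesterol synthesis. It was -0.096 to 0.379 for contractile genes and -0.068 to 0.24 for ribosome biogenesis.

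Heat shock and immediate early genes were shifted downward with pA-VMO. The 14 heat shock genes all lay below control, with a mean of -0.16 (camera adjusted p = 1.1e-07). Of these 0 fell over all genes tested and 5 fell when adjusted over the list alone, and Dnajb1 and Hspb1 lay at -0.27 and -0.24 (both adjusted p = 0.314), with Dnajb1 at -0.15 without control replicate 2. Of the 32 immediate early genes 26 lay below control, with a mean of -0.13 (camera adjusted p = 6.89e-09), and 11 fell when adjusted over the list alone while 0 fell over all genes. Btg2 lay at -0.35 (adjusted p = 0.251), the RNA-decay factor Zfp36 at -0.33 (adjusted p = 0.228) and the phosphatase Dusp1 at -0.31 (adjusted p = 0.204). Both lists had an adjusted p = 0.47 with an estimated correlation. The 95% interval from the spread between arrays was -0.246 to -0.08 for heat shock genes and -0.183 to -0.069 for immediate early genes. Smaller downward shifts were seen in the 24 TGF-beta targets with a mean of -0.04 and Tgfbi at -0.33 (adjusted p = 0.204), in the 18 p53 targets with a mean of -0.06, and in the 24 Hedgehog, Wnt and BMP readouts with a mean of -0.06 and Sfrp4 at -0.50 (adjusted p = 0.228). Over all genes tested 0 members of these lists fell, and 1, 0 and 3 fell when adjusted over the list alone. The 95% intervals of these lists from the spread between arrays included 0. Their camera adjusted p values were 0.0406, 0.0406 and 0.0431, and their adjusted p with an estimated correlation 0.482, 0.482 and 0.473. Without pA-VMO replicate 1 they were 0.388, 0.507 and 0.0924, and without control replicate 1 they were 0.304, 0.274 and 0.132; the last list also had 0.0528 without pA-VMO replicate 2 and 0.0591 without either single 5'ss-VMO array.

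Markers of macrophages were shifted upward with pA-VMO and those of FAPs downward. The 17 macrophage markers had a mean change of 0.18 (camera adjusted p = 8.84e-05; adjusted p = 0.473 with an estimated correlation), with 0 called over all genes and 1 when adjusted over the list alone. Cd68 lay at 0.35, the protease Ctss at 0.30 (adjusted p = 0.351) and Tyrobp at 0.22 (adjusted p = 0.313), with Ctss at 0.14 and 0.46 without control replicates 1 and 2. The 19 FAP markers had a mean of -0.11 (camera adjusted p = 0.000156; adjusted p = 0.47 with an estimated correlation), with 0 called over all genes and 3 lower when adjusted over the list alone. Dpp4 lay at -0.45 (adjusted p = 0.204), Clec3b at -0.31 (adjusted p = 0.231) and Cd34 at -0.25 (adjusted p = 0.284). The interferon-stimulated list had a mean of 0.12 (camera adjusted p = 0.000156; adjusted p = 0.482 with an estimated correlation), with 21 of 26 members positive, 0 called over all genes and 2 higher when adjusted over the list alone. Mx1 lay at 0.53 (adjusted p = 0.278), and at 0.32 without control replicate 1 and 0.36 without pA-VMO replicate 2. Of 12 neutrophil markers on the array 5 passed the filter, with a median log2 level of 5.77 where the floor was 5.209. These 5 had a mean change of 0.22 (camera adjusted p = 0.00389, adjusted p = 0.473 with an estimated correlation). Over all genes 0 were called and over the list alone 2, and Il1b lay at 0.50 (adjusted p = 0.235). The 10 tenocyte markers had a mean of -0.21 (camera adjusted p = 0.0334; adjusted p = 0.482 with an estimated correlation), with 1 lower over all genes and 2 when adjusted over the list alone. Below control lay Kera, Tnmd at -0.43 (adjusted p = 0.432) and Comp at -0.38 (adjusted p = 0.204), while the median of the list was -0.04. Without pA-VMO replicate 1 Tnmd lay at -0.23. Judged by the spread between arrays, the 95% intervals included 0 for the macrophage (-0.033 to 0.387), interferon (-0.06 to 0.3) and tenocyte (-0.494 to 0.085) lists. Those of the FAP and neutrophil lists did not. Without control replicate 1 the macrophage, interferon, neutrophil and tenocyte lists had mean changes of 0.096, 0.07, 0.182 and -0.163 and were not called. Leaving out control replicate 2 instead gave 0.257 for the macrophage list and 0.17 for the interferon list. The neutrophil list also lost its call without pA-VMO replicate 2 (adjusted p = 0.0875), and the tenocyte list without pA-VMO replicate 1 (adjusted p = 0.186). Endothelial, lymphocyte, satellite cell, muscle fibre, pericyte and Schwann cell markers were not called (camera adjusted p = 0.0782, 0.0811, 0.889, 0.962, 0.362 and 0.64). The 95% interval of the pericyte list, with an SD of 0.008 between arrays, was still above 0 (0.028 to 0.081). The collagen, matrix and matrix protease lists had means of 0.04, -0.02 and -0.07 and were not called (camera adjusted p = 0.311, 0.25 and 0.0782).

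Set directly against each other, the 2 reagents differed in 9 of 14953 genes, of which 7 were lower with pA-VMO and 2 higher. Saa3, an acute phase serum amyloid gene, differed by -1.43 ± 0.163 (log2, SE; 2.70-fold, adjusted p = 0.0249), with group means of 8.31 with control VMO, 7.42 with pA-VMO and 8.86 with 5'ss-VMO. Ifi208 differed by -1.30 ± 0.1 (2.46-fold, adjusted p = 0.00533), and its means were 6.47, 6.48 and 7.78 in the same order. Ifi206 differed by -0.77 (adjusted p = 0.00677), Phf11a and Ifit3b by -0.73 (adjusted p = 0.0433 for each), Lrrn1 by -0.72 (adjusted p = 0.0212) and Ms4a4c by -0.65 (adjusted p = 0.0249). The potassium channel gene Kcnk9 was higher by 0.51 (adjusted p = 0.0433). Snora44, a small nucleolar RNA that the naming rule leaves out and that was chosen after its values were seen, had the largest difference, 2.14 (4.40-fold, adjusted p = 0.00677), since it differed from control by -2.12 with 5'ss-VMO and by 0.02 with pA-VMO. Of these 9 genes 7 were also called with 5'ss-VMO against control. The count was 1 without pA-VMO replicate 1, 3 without 5'ss-VMO replicate 1 and 18 without 5'ss-VMO replicate 2, and of the 8 genes the rule names only Ifi208 was called whichever array was left out.

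The other genes singled out between the reagents did not pass the test. Below 5'ss-VMO lay Chrna1 at -0.69, Trim30d at -0.60, Adamts6, a matrix protease, at -0.59 and Tcim at -0.51 (adjusted p = 0.0513 for each), and Usp18, which removes the ubiquitin-like Isg15, at -0.46 (adjusted p = 0.0626). Above it lay the thrombomodulin gene Thbd at 0.52 and Eif4e1b at 0.53 (adjusted p = 0.0626 for both), Bard1 at 0.43, Isx and Klk1b9 at 0.46, Negr1 at 0.40, Alas2 and Nkx2-2 at 0.39, and Slc6a18, Zfp385c and Frem2 at 0.37 (adjusted p = 0.0684 to 0.0687). With the mean over the probe sets of a gene Eif4e1b lay at 0.22 and Bard1 at 0.16. At an adjusted p of 0.10 there were 252 genes in place of 9.

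As groups, interferon-stimulated, heat shock and immediate early genes were lower with pA-VMO than with 5'ss-VMO. On the interferon list 26 of 26 members were lower, with a mean difference of -0.32 (camera adjusted p = 2.9e-21); 0 of them fell over all genes tested and 24 fell when adjusted over the list alone. The heat shock list differed by -0.24 with 14 of 14 members lower, 0 of them called over all genes and 10 when adjusted over the list alone (camera adjusted p = 5.57e-09). Hspb1 lay at -0.51 and Hspa1a at -0.46 (both adjusted p = 0.0626). The immediate early list differed by -0.15 with 0 of 32 members lower over all genes and 14 when adjusted over the list alone (camera adjusted p = 1.03e-08), and Zfp36 and Atf3 both lay at -0.43 (adjusted p = 0.0684 and 0.0687). These 3 lists had an adjusted p = 0.317 with an estimated correlation. Their 95% intervals from the spread between arrays were -0.497 to -0.136, -0.318 to -0.151 and -0.21 to -0.096. PDGF ligands, receptors and adaptors differed by -0.10 (camera adjusted p = 0.00573; adjusted p = 0.349 with an estimated correlation), with 14 of 16 members lower, 0 of them called over all genes or when adjusted over the list alone. The ligand genes lay at -0.33 for Pdgfc (adjusted p = 0.213) and at -0.22 for Pdgfd (adjusted p = 0.278). Without 5'ss-VMO replicate 2 Pdgfc lay at -0.19, and without pA-VMO replicate 1 Pdgfd lay at -0.12. The 30 cytokines and chemokines differed by -0.14 (camera adjusted p = 0.000147; adjusted p = 0.537 with an estimated correlation), with 0 called over all genes and 8 lower when adjusted over the list alone. Ccl8 lay at -0.52 (adjusted p = 0.0626) and the nitric oxide synthase Nos2 at -0.50 (adjusted p = 0.0687). By the spread between arrays, the 95% interval of the cytokine list included 0 (-0.296 to 0.025), while that of the PDGF list did not.

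Adipocyte genes were shifted the other way, with 15 of 16 members higher with pA-VMO than with 5'ss-VMO and a mean difference of 0.12 (camera adjusted p = 0.00532; adjusted p = 0.317 with an estimated correlation). The lipid droplet gene Plin1 lay at 0.33 (adjusted p = 0.158), and 0 members were called by either adjustment. The 8 Schwann cell markers, with 0 called in either way, were also higher, by 0.13 (camera adjusted p = 0.0081; adjusted p = 0.317 with an estimated correlation). The 14 satellite cell markers differed by -0.19 (camera adjusted p = 0.0013; adjusted p = 0.537 with an estimated correlation). The 17 macrophage markers differed by -0.11 (camera adjusted p = 0.0244; adjusted p = 0.639 with an estimated correlation) and the 17 muscle fibre markers by -0.12 (camera adjusted p = 0.0244; adjusted p = 0.679 with an estimated correlation). Over all genes 0 of these markers were called, and 4, 2 and 5 were lower when adjusted over the list alone. Among them Mymk lay at -0.49 and C1qa at -0.36 (adjusted p = 0.0687 for both), and Actc1 at -0.68 (adjusted p = 0.0684). The 95% intervals between arrays included 0 for the satellite cell (-0.405 to 0.024), macrophage (-0.325 to 0.096) and fibre (-0.317 to 0.068) lists. Those of the adipocyte and Schwann lists did not. The fibre list had an adjusted p of 0.096 without pA-VMO replicate 2 and 0.536 with a filter at the 50th percentile. With that filter the macrophage list had 0.264, and the Schwann list had 0.0682 with no filter. The 22 glycolysis genes, with 0 called over all genes and 2 lower when adjusted over the list alone, differed by -0.12 (camera adjusted p = 0.0145; adjusted p = 0.743 with an estimated correlation). This rested on 1 array, since without 5'ss-VMO replicate 2 the mean difference was 0.016 (adjusted p = 0.74). FAP markers and collagens differed by 0.01 and -0.05 and were not called (camera adjusted p = 0.813 and 0.179), nor were the 2 cell cycle lists (camera adjusted p = 0.384 and 0.179).

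**Figure D2:**
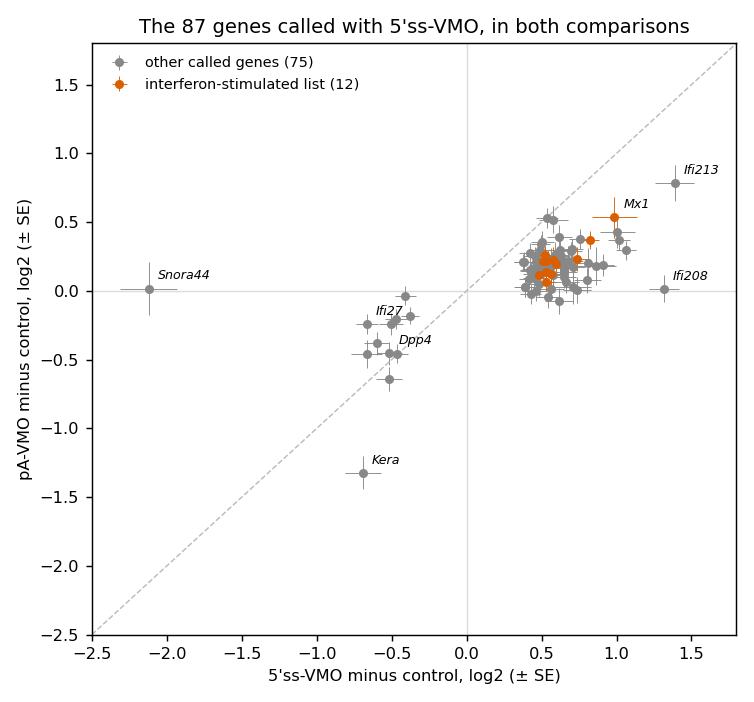
Change against control with 5'ss-VMO (x axis) and with pA-VMO (y axis), both in log2 with SE, for the 87 genes called with 5'ss-VMO; orange points are the 12 called members of the interferon-stimulated list, and the dashed line marks equal change. Ifi208 lies at 1.32 and 0.02 and Kera at -0.69 and -1.32.

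The changes with the 2 reagents were compared across genes. Of the 75 genes that rose with 5'ss-VMO, 71 lay above control with pA-VMO as well; their median change was 0.57 with 5'ss-VMO and 0.20 with pA-VMO. Of the 12 that fell, 11 lay below control with pA-VMO, with medians of -0.52 and -0.31. These genes were chosen for their change with 5'ss-VMO and share the control arrays, so both the agreement in sign and the smaller size with pA-VMO are partly built in, and no value without an effect was computed for them. Kera was the 1 gene called in both comparisons with control. Over all 14953 genes the 2 changes had a Pearson r of 0.398 and the same sign in 62.2%, where genes are not independent replicates. Both comparisons use the same 2 control arrays, and simulated groups with no effect against shared controls gave an r of 0.501 and the same sign in 66.7%. The observed covariance was 0.00621 against a simulated 0.00423, a difference of 0.00198. With a different control array for each reagent the covariance was 0.000697 or 0.00332, depending on which array went with which reagent. Both values lay below 0.00621. Noise in shared control arrays adds to the covariance by construction, so the split values lie lower on average whatever the reagents do. The observed r and share of equal signs were no higher than the simulated groups with no effect gave. The r was 0.545 without control replicate 1.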

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

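The tests of explanations in this part were chosen after the results were seen; the cyclic loess setting they draw on had been chosen earlier. In a group of 2 arrays both lie equally far from their mean, so a test cannot say which of them is off. Among the 13767 probe sets outside the named genes, 0 were called by limma in any comparison. The fit behind this count, of all 35556 probe sets together, also called 0 of the named ones. It therefore cannot show that the probe sets outside the named genes did not change. In that fit 2692, 3192 and 3987 probe sets had an unadjusted p under 0.05 for pA-VMO against control, 5'ss-VMO against control and pA-VMO against 5'ss-VMO.

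The first pattern is the rise of interferon-stimulated genes with 5'ss-VMO. A shift that depends on brightness and was left by the normalization is argued against: after cyclic loess the mean change of the list was 0.427 (95% interval 0.209 to 0.644). More macrophages among the isolated cells stay open, since the macrophage markers rose too; how the FAPs were isolated is not given in the sources used here. A gene that FAPs also express would then rise by no more than the macrophage markers; the interferon list exceeded the 7 brighter ones of 17 markers by 0.084 against control (interval -0.242 to 0.41) and by 0.194 against pA-VMO (interval -0.132 to 0.52), and all 17 by 0.146 (0.011 to 0.28) and 0.202 (0.068 to 0.337), where dim markers are compressed. A response of the cells to the oligomer itself or to the blocked site was not tested, with 1 reagent per site.

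The second pattern is the upward shift of cell cycle genes with both reagents. A single low control array as the cause is argued against: without the lower control array the G2 and M list was still shifted by 0.226 with pA-VMO and 0.19 with 5'ss-VMO, where the control arrays lay 0.054 apart. The 95% intervals of the shift from the spread between arrays, -0.05 to 0.557 with pA-VMO and -0.086 to 0.52 with 5'ss-VMO, include 0, so they do not exclude that both control arrays lay low by chance. More macrophages cannot be told apart from a change in the FAPs: the G2 and M list exceeded the macrophage markers by 0.077 with pA-VMO (interval -0.349 to 0.503) and by -0.074 with 5'ss-VMO. A biological explanation, faster cycling of FAPs after either reagent or slower cycling after the control VMO, stays open as a hypothesis.

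The third pattern is the downward shift of heat shock and immediate early genes with pA-VMO. A brightness-dependent shift is argued against, since after cyclic loess the mean change was -0.153 (interval -0.276 to -0.031) for heat shock genes and -0.117 for immediate early genes. Different handling of the muscles before lysis, to which both lists are known to respond, cannot be told apart from an effect of the reagent: handling is not recorded in the sources used here, and that 4 of 4 list values of the pA-VMO arrays lay below both control arrays only restates the shift. An effect of pA-VMO on signalling to these genes stays open as an untested biological explanation.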

How the results depend on the processing

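Alternatives were fixed before the data were examined, except the block with crossed numbers, the count of interferon members called and the fit of all probe sets together, which were added after seeing the data. Where no cause is named below, the cause was not tested. Genes called for pA-VMO against control (1), 5'ss-VMO against control (87) and pA-VMO against 5'ss-VMO (9) became 0, 24 and 3 with no filter, which brings in dim genes and more tests. They became 1, 181 and 102 with a filter at the 50th percentile, 49, 265 and 186 with trend and robust eBayes, and 1, 197 and 252 at an adjusted p of 0.1. The fit of all probe sets together called 0, 0 and 0. For pA-VMO against 5'ss-VMO cyclic loess called 5, array weights 14 and the mean over probe sets 15. With 1 array left out the counts ran from 0 to 2, from 8 to 76 and from 1 to 18. The interferon members called with 5'ss-VMO (12) were 2 with no filter, 21 with trend and robust eBayes and 1 to 12 with an array left out.

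The replicate numbers share no stated batch, and arrays of the same number did not deviate together (correlation of deviations -0.102 for control and pA-VMO, 0.0207 for control and 5'ss-VMO and -0.0345 for pA-VMO and 5'ss-VMO). With the number as a replicate block 1, 90 and 23 genes were called, and 75 of the 87 and all 9 of the main calls were among them. With the pA-VMO numbers crossed, 5 genes were called against control.

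Called lists (15, 13 and 11) became 0, 0 and 0 with an estimated correlation and 0, 2 and 6 with fry, and ran from 8 to 17, 10 to 15 and 11 to 16 with an array left out. Called lists kept their direction in all of these fits but 1: glycolysis between the reagents ran from -0.256 to 0.016 with an array left out, and was 0.016 without 5'ss-VMO replicate 2. Other calls of lists were lost as follows (adjusted p). With a filter at the 50th percentile these were, for pA-VMO against control, TGF-beta targets (0.103) and p53 targets (0.218); for 5'ss-VMO against control, muscle fibre (0.185), collagens (0.0842) and cytokines (0.0866); and between the reagents, macrophage (0.264), muscle fibre (0.536) and glycolysis (0.0514). With cyclic loess they were, for pA-VMO against control, tenocyte (0.0605), TGF-beta (0.175), p53 (0.0747) and Hedgehog, Wnt and BMP (0.0605), and Schwann (0.0569) for 5'ss-VMO against control. The Schwann list was lost with no filter for 5'ss-VMO against control (0.0767) and between the reagents (0.0682), and the Hedgehog, Wnt and BMP list for pA-VMO against control in the fit of 4 arrays (0.0591). Pdgfra had changes near 0 whose sign varied: for pA-VMO against control -0.005 after median centring and -0.064 to 0.066 with an array left out, for 5'ss-VMO against control 0.012 after cyclic loess and -0.07 to 0.06, and for pA-VMO against 5'ss-VMO -0.011 to 0.022; none was called. The correlation of the 2 changes ran from 0.284 to 0.545 with an array left out. Among the named genes, only Snora44 and Ifi208 with pA-VMO against control, both near 0, changed sign, with ranges of -0.293 to 0.327 and -0.097 to 0.129 with an array left out. Scalings moved the median of all genes by no more than 0.021 (log2).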

Other observations

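The tests of name stems, the split of the control arrays and Snora44 were chosen after the results were seen, while the gene lists, cyclic loess and the correlation of the 2 changes were planned. Genes that share a name stem were compared with all others by camera in 474 stems of at least 5 tested genes, none of them fixed beforehand. With 5'ss-VMO the guanylate-binding proteins (Gbp, 8 genes, median change 0.49, 3 called, camera adjusted p = 2.92e-09), the Ms4a membrane proteins (11 genes, median 0.48, 5 called, adjusted p = 0.000122), the Parp family (11 genes, median 0.16, 1 called, adjusted p = 0.000348) and the Slfn family (7 genes, median 0.20, 2 called, adjusted p = 0.00172) were shifted upward as groups. The Ifi stem moved less uniformly, with a median of 0.11 over 11 genes, 4 called higher and 1, Ifi27, called lower (adjusted p = 0.00882). Proteasome subunits were shifted by less, with medians of 0.14 for Psma, 0.11 for Psmb and 0.11 for Psmd genes (adjusted p = 0.013, 0.00567 and 0.00615). Shifts of that size were not particular to them. Medians were 0.13 for Nup, 0.12 for Srsf and 0.11 for Lsm genes (camera adjusted p = 0.0183, 0.0356 and 0.0258). Downward shifts included Kcnj, Krt and Prss genes, with medians of -0.17, -0.09 and -0.09 (camera adjusted p = 0.00882, 0.00241 and 0.0111). All of these had an adjusted p = 0.914 with an estimated correlation. The Ms4a stem was shifted upward with pA-VMO as well, with a median of 0.21 and 0 of 11 genes called. There its camera adjusted p was 0.00199, and 0.991 with an estimated correlation. The Gbp, Ms4a and Slfn genes sit in families of close paralogs, so their members are not independent readings.

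Abca lipid transporters lay below control with both reagents, with a median of -0.13 over 11 genes with pA-VMO (camera adjusted p = 0.000945) and -0.15 with 5'ss-VMO (adjusted p = 0.00209); the adjusted p was 0.991 and 0.914 with an estimated correlation. The C1qtnf genes had a median of -0.23 over 7 genes with pA-VMO (adjusted p = 0.0134; adjusted p = 0.991 with an estimated correlation). Some stems with 0 members called were shifted upward with pA-VMO relative to 5'ss-VMO: keratins (Krt, 34 genes, median 0.14, adjusted p = 0.00068), serine proteases (Prss, 28 genes, 0.15, adjusted p = 0.00068) and defensins (Defb, 13 genes, 0.19, adjusted p = 0.0208), all with an adjusted p = 0.859 with an estimated correlation. The lowest tercile of all genes by level had a median difference of 0.08 in that comparison and the highest tercile one of -0.03, and after cyclic loess these medians were 0.00 and 0.00. Dim genes that are higher with pA-VMO than with 5'ss-VMO, Kcnk9 among them, are therefore open to this trend in the deposited values; Kcnk9 itself lay at 0.42 after cyclic loess and missed the threshold there.

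A hypothesis of opposite action was tested, because the 2 reagents were designed to move the short Pdgfra transcript in opposite directions. If they moved most genes in opposite directions, the covariance of the 2 changes against control would lie below the value that shared controls give with no effect. The observed covariance was 0.00621, above the highest of the simulated values, 0.00454. The r of 0.398 and the same sign in 62.2% lay below the simulated ranges, 0.482 to 0.519 and 65.7% to 67.8%, but separate effects of the reagents lower both without opposite action. With a different control array for each reagent, which takes the shared noise away, the covariance was 0.000697 or 0.00332, and would be near 0 without effects. Both values are positive but differ by more than the lower one, so opposite action on most genes cannot be told apart from separate effects of the reagents. The FAP, macrophage, cell cycle and contractile lists moved the same way with both reagents, while heat shock genes had a mean change of -0.16 with pA-VMO and 0.07 with 5'ss-VMO, of which the latter was not called (camera adjusted p = 0.0714). For these lists the control arrays were not split, so effects common to the 2 reagents and noise of the 2 shared control arrays cannot be told apart.

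Snora44 had the largest change of any called gene. It lay at 9.84 and 10.46 on the control arrays, 10.14 and 10.20 on the pA-VMO arrays and 8.25 and 7.81 on the 5'ss-VMO arrays, a difference from control of -2.12 with 5'ss-VMO (4.35-fold lower, adjusted p = 0.00342). Snora33 and Snora41 were called the other way in that comparison, at 0.651 and 0.65 (limma adjusted p = 0.0118 and 0.0157), so called small nucleolar RNAs did not all fall. All of them were chosen after their values were seen, and how well small nucleolar RNAs are recovered in each preparation was not tested.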
